A study of Homo sapiens with 4 samples.

How the data were processed

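Values were compared for 4 libraries from a breast cancer cell line grown in DMEM with serum, per the labels. The sample labels name the cell line as MDA-MB-231 and the growth protocol names MDA-MB-231Br, and which of them was used is not settled here. There were 2 libraries of input RNA and 2 of RNA recovered with an anti-YTHDF3 antibody from Santa Cruz Biotechnology. Library preparation used a stranded Illumina mRNA kit on poly(A)-selected RNA, per the labels' protocols. The inputs nevertheless held much small structural RNA and histone mRNA without a poly(A) tail, and the RIP libraries held little of either. Whether both groups were selected alike is therefore not settled here. The extraction text in the labels speaks of embryos and of an antibody against m6A, which matches neither the cell line nor the antibody given for the RIP samples, so which protocol was followed is not settled here. Samples were grouped by their titles. Each title also ends in a suffix that is shared by one input and one RIP library, and the labels do not say what it stands for. Within each group, the libraries are numbered 1 and 2 in accession order, which gives the same number to libraries with the same suffix.

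The deposited table holds 1 value per gene and library. No header or label names the unit, and it was taken from the values. These are not whole numbers, their sums differ between the groups (700141 and 690869 in the inputs, 301226 and 301483 in RIP), and after multiplication by the exon length of each gene the sums are close to each other (1621380, 1566173, 1688125 and 1733992), which is what the FPKM scale gives. The authors thus deposited FPKM values, reads per kilobase of gene length scaled to the total reads of the library, as far as the values show. HISAT2 and the GRCh38 (hg38) build are named in the submitters' processing notes. The version of HISAT2, the program that counted reads, the annotation, any filter and the use of strand are not given in the sources used here. FPKM corrects for library size and gene length only. A group of RNAs that takes a large share of a library's reads lowers the values of all other genes there. By length-weighted signal, small structural RNAs held 5.43% and 5.72% of the inputs, and chromosome 1 held 35.9% of RIP 2. Fold changes between RIP and input thus depend on scaling, and other scalings are reported beside the main one.

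Of 36217 rows, 14 with a repeated identifier were dropped, which left 36203 Ensembl identifiers. Of these, 36125 are in GENCODE release 29 on GRCh38, from which gene classes, positions and transcript lengths were taken, and 78 are not. For 27 genes the symbol had been turned into a date and was restored through the identifier. An exact 0 can be a failed estimate in such a table, since widely used genes are also at 0 in some libraries, so such genes are described as listed at 0 with each library's value, and no fold is given against a group at 0. All 4 libraries were at 0 for 17707 identifiers.

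Depth is not stated. The commonest low value of FPKM times exon length in kilobases among single-transcript genes was assumed to be 1 read, from 144 to 186 genes per library. It gave a relative depth of about 6140000, 7310000, 10400000 and 3110000 reads for input 1, input 2, RIP 1 and RIP 2. Only 32.7% to 34.2% of low values came out whole within 0.03 of a read, so reads were not recovered and no count test was run. No counting interval is given for single genes, and a gene listed at 0 in RIP 2 was tested at the lowest depth.

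Genes at 1 FPKM or more in at least 2 of the 4 libraries were kept (12848). RIP was compared with input on log2(FPKM + 1) with limma 3.58.1 (empirical Bayes with a mean-variance trend) in R 4.3.3, with all 4 libraries and no block, and two-sided p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. The same test was run on simulated data with the means of 12147 genes, 200 of them changed. The spread was that of these libraries (median SD 0.367 in input, 0.561 in RIP). The test recovered 48% of 4-fold and 98% of 8-fold changes, with 16 false calls and no wrong sign. Even if all 200 changed genes had been called, 16 false calls would be a larger share of the calls than 0.05. The calls reported here may therefore hold more false ones than the threshold of 0.05 states.

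Gene lists (28) were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 3 measured genes. With the correlation estimated from the data instead, none of the lists passed, in a form of the test that has only the few residual degrees of freedom of these libraries. The lists, the comparison, the filter, the test and the alternatives were fixed before the data were examined, except where the text says otherwise. The genes named are all measured transcripts that the study singled out, the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among those that passed, moved in the same direction with both suffixes and had a mean in the upper part of the genes tested (above the median), and from each list at most 2 genes with the smallest p and 1 more in the other direction. Genes named outside this rule are marked in the text.

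The alternatives were quantile normalization, centring of each library on its median, no filter beyond a value above 0, a filter at 5 FPKM, a pseudocount of 0.1, limma without the trend, the title suffix as a replicate block, and each library left out in turn. After RIP 2 was seen to carry an excess from chromosomes 1 and 10, testing only genes outside these chromosomes and adjusting RIP 2 by position were added. The former test was fitted and adjusted anew on its own genes, so its calls are not a subset of the main calls. The adjustment subtracted, from the log2 values of RIP 2, the median difference from RIP 1 in bins of 10 Mb on chromosomes 1 and 10 (the chromosome's median in bins with under 10 genes) and the overall median difference elsewhere. Matching, partial correlations and bootstrap intervals in the closing section used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, on the longest transcript of each protein-coding gene in GENCODE release 29. The bootstrap resampled genes with the libraries held fixed, so none of its intervals covers the variation between libraries. Figures were drawn with matplotlib 3.10.9. Some single-gene and gene-family results are not reported here.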

Results

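The sample labels name the breast cancer cell line MDA-MB-231, and the growth protocol names MDA-MB-231Br, a derivative of it selected for growth in the brain. In RNA immunoprecipitation followed by sequencing (RIP-seq), an antibody pulls down a protein with the RNA bound to it, and that RNA is compared with the starting material, called input. Here the antibody was raised against YTHDF3, a cytoplasmic protein that binds mRNA carrying N6-methyladenosine (m6A). The series holds 4 libraries, 2 of input and 2 of YTHDF3 RIP, each given as FPKM per gene. The labels do not say whether libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. By its title, the study concerns YTHDF3 and m6A-carrying transcripts linked to metastasis, and RIP against input is the only comparison the design holds. A RIP with a non-specific antibody was not analysed here, so the comparison does not separate binding to YTHDF3 from other RNA retained in the procedure.

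Total read counts are not in the table. With the commonest low value assumed to be 1 read, 1 read per kilobase of transcript was worth 0.163 FPKM in input 1, 0.137 in input 2, 0.0964 in RIP 1 and 0.322 in RIP 2. This corresponds to relative depths of about 6140000, 7310000, 10400000 and 3110000 reads. RIP 2 was therefore the shallowest library, and it had 13905 genes above 0, against 16240 in input 1, 16126 in input 2 and 16604 in RIP 1. Across the 12848 genes tested, log2 values correlated with Pearson's r = 0.944 between the inputs and 0.824 between the RIP libraries. Between an input and a RIP library r ranged from 0.447 to 0.506. These are correlations across genes, which are not independent replicates.

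The RIP libraries held a larger share of protein-coding transcripts than the inputs. Protein-coding genes made up 92.7% and 94.9% of the summed FPKM in RIP 1 and RIP 2, against 46.1% and 46.3% in input 1 and input 2. The annotation class misc_RNA, which holds the 7SL RNA of the signal recognition particle, took 26.9% and 22.2% of the inputs and 0.6% and 0.18% of the RIP libraries. Small nuclear RNAs of the spliceosome took 9.09% and 12.5% of the inputs and 1.0% and 0.37% of the RIP libraries. Because FPKM divides by length, these short RNAs weigh more here than in reads. After multiplication by exon length, an approximate share of reads, protein-coding genes held 89.21% and 89.83% of the inputs and 97.55% and 98.25% of the RIP libraries, and small structural RNAs 5.43% and 5.72% of the inputs and 0.09% and 0.03% of the RIP libraries. Of the 14 structural RNAs measured from a list fixed beforehand, 12 were lower in RIP and none was higher (13 lower when adjusted over the list alone), with a median log2 fold change of -5.92 (camera, adjusted p = 1.47e-05, and adjusted p = 0.438 with an estimated correlation). This median was -4.10 after quantile normalization, with 9 lower, -4.62 without RIP 2 and -7.00 without RIP 1. RPPH1, the RNA of ribonuclease P, had 29367 and 33619 FPKM in the inputs and 234 and 47.4 FPKM in RIP. RN7SL2, a 7SL RNA gene, had 56168 and 18946 FPKM in the inputs and 164 and 99.98 FPKM in RIP. RN7SL2 shares reads with near-identical copies, so its own level is uncertain. A difference in poly(A) selection between input and RIP could also lower these structural RNAs in RIP, and it was not tested.

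**Figure D1:**
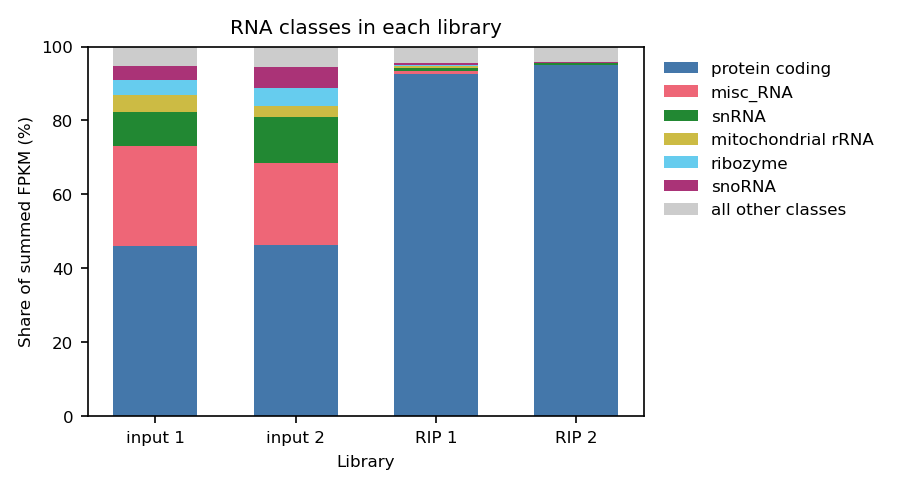
Each bar is 1 library and shows the share of summed FPKM, in percent, held by each RNA class of the annotation. Protein-coding genes hold 46.1% and 46.3% of the inputs and 92.7% and 94.9% of the RIP libraries.

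Of the genes on the lists, 209 of 392 ZNF genes and 25 of 52 chromatin regulators were higher in YTHDF3 RIP than in input, and 71 of 77 ribosomal protein genes, 53 of 62 nuclear genes of the respiratory chain and 47 of 54 replication histone genes were lower. None of these lists passed in camera with an estimated correlation (adjusted p = 0.438 for each). At a Benjamini-Hochberg adjusted p under 0.05 in limma, 1981 genes were higher and 3126 were lower among the 12848 tested, and 1974 and 3116 of them differed at least 2-fold. Folds are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Of the genes called lower, 149 were listed at 0 in both RIP libraries, and of those called higher, 12 were listed at 0 in both inputs. The balance of the directions depended on scaling. Higher genes made up 38.8% of the calls on the deposited values, with a median log2 fold change of -0.10 over all genes tested, and 52.1% after quantile normalization (3085 higher, 2831 lower, median 0.13). With either input left out no gene passed (limma; 737 higher and 2299 lower at an unadjusted p under 0.05 without input 1, 608 and 2257 without input 2), and without RIP 2 the count of higher genes was 3515.

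RIP 2 carried an excess of signal from chromosomes 1 and 10 that no other library showed. Chromosome 1 held 35.9% of its length-weighted signal, against 9.2% in input 1, 9.48% in input 2 and 10.6% in RIP 1. The median log2 difference of RIP 2 from RIP 1 was 1.67 for the 1138 protein-coding genes tested on chromosome 1 and 0.67 for the 433 on chromosome 10, and it lay between -0.91 and -0.34 on the other autosomes and X. In bins of 10 Mb, the difference on chromosome 10 was -0.47, -0.34 and -1.15 from 110 Mb on, within or below that range, so the excess does not reach the end of chromosome 10. Many genes on chromosomes 1 and 10 thus have RIP means raised by 1 library, and each one named below is marked by its chromosome. Because FPKM is scaled to the total reads of a library, the excess also lowers the values of all other genes in RIP 2. Among the 10937 genes outside both chromosomes, 1814 were higher and 3119 lower, with a median log2 fold change of -0.245. RIP 2 was not rescaled for these counts, so they lean towards lower. After RIP 2 was adjusted for position, an alternative chosen after this excess was seen, 3575 genes were higher and 3512 lower.

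**Figure D2:**
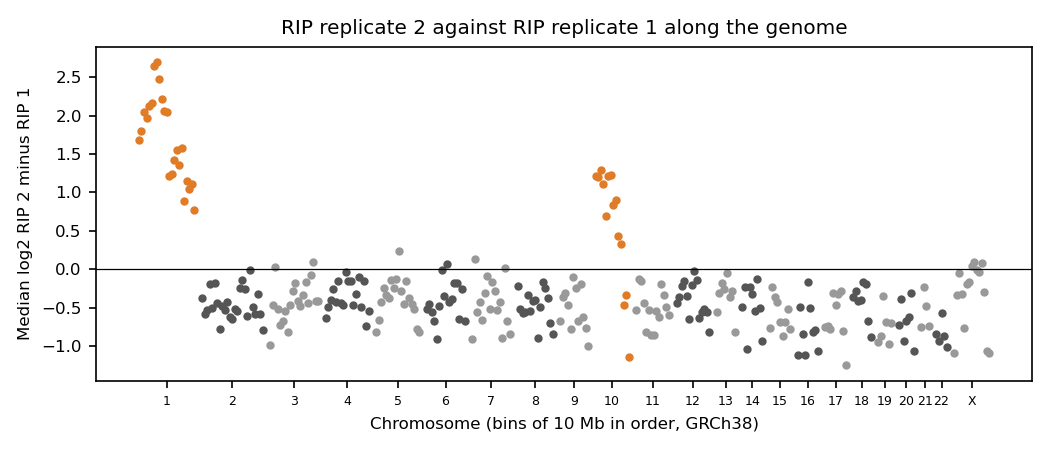
Each point is the median log2 FPKM of RIP 2 minus RIP 1 over the protein-coding genes of a 10 Mb bin, with bins in order along each chromosome of GRCh38. Bins of chromosomes 1 and 10 are in orange, and chromosome 1 reaches a median of 2.64 between 60 and 90 Mb.

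Of the 5 transcripts that the study itself singled out as YTHDF3 targets, 4 were higher in RIP and the other missed the threshold. These were chosen by the study on these libraries, so their direction is not independent evidence, and the same holds for the 4 that passed when adjusted over the list alone. The list had a median log2 fold change of 2.45, or 1.77 without RIP 2 (camera, adjusted p = 0.00808, and adjusted p = 0.438 with an estimated correlation). The mRNA of YTHDF3 itself (ENSG00000185728, chromosome 8, 63168553 to 63212786 in GRCh38) rose from 12.0 ± 2.54 FPKM in input to 74.1 ± 2.38 FPKM in RIP (SD, n = 2), a log2 fold change of 2.54 with SE 0.45 and adjusted p = 0.0122. VEGFA, which encodes the angiogenic factor VEGF-A (ENSG00000112715, chromosome 6, 43770184 to 43786487), had 8.90 ± 1.5 FPKM in input and 58.5 ± 35.9 FPKM in RIP (SD, n = 2), with a log2 fold change of 2.45, SE 0.58 and adjusted p = 0.0221. VEGFA had 1.79 without RIP 1 and 3.11 without RIP 2, and missed the threshold with no filter on low values (adjusted p = 0.0506). GJA1, the gap junction protein connexin 43 (ENSG00000152661, chromosome 6, 121435577 to 121449727), had 13.3 ± 2.14 FPKM in input and 50.9 ± 6.03 FPKM in RIP (SD, n = 2), with a log2 fold change of 1.87, SE 0.45 and adjusted p = 0.0234. ST6GALNAC5, a sialyltransferase linked to passage across the blood-brain barrier (ENSG00000117069), lies on chromosome 1 (76867441 to 77065711). It had 1.43 and 1.67 FPKM in the inputs, 6.14 FPKM in RIP 1 and 33.5 FPKM in RIP 2. Its log2 fold change was 2.62 (SE 0.79, adjusted p = 0.041), and without RIP 2 it was 1.49. It missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0507) and with no filter on low values (adjusted p = 0.0944). EGFR, the epidermal growth factor receptor (ENSG00000146648, chromosome 7, 55019021 to 55211628), had 111 ± 50.3 FPKM in input and 291 ± 99.8 FPKM in RIP (SD, n = 2). Its log2 fold change of 1.42 (SE 0.60) did not pass over all genes (adjusted p = 0.0988), and was 1.77 without RIP 2.

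**Figure D3:**
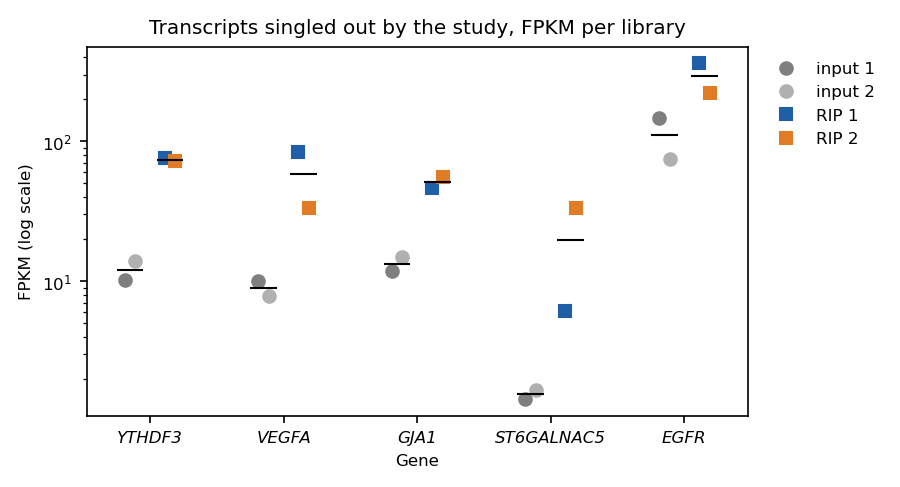
FPKM of the 5 transcripts singled out by the study, on a log axis, with 1 point per library and a black line at the mean of each group of 2. The RIP libraries lie above the inputs for each of the 5, and the RIP values of ST6GALNAC5, on chromosome 1, are 6.14 and 33.5 FPKM.

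The largest increases by the rule fixed beforehand were led by SRXN1, which encodes sulfiredoxin, an enzyme that restores oxidised peroxiredoxins. SRXN1 was listed at 0.179 FPKM in input 1 and at 0 in input 2, and at 174 and 75.4 FPKM in RIP. Of the 10 genes with the largest increase, 8 lie on chromosome 1, among them LRRC8D, a subunit of volume-regulated anion channels, EXO5, a DNA exonuclease, the transcriptional repressor SPEN, CSF1, which encodes macrophage colony-stimulating factor, RRAGC, a GTPase of amino acid sensing by mTORC1, and FAM69A. The log2 fold changes of these named genes ran from 4.07 for FAM69A to 4.92 for LRRC8D, and without RIP 2 from 3.16 for RRAGC to 4.71 for LRRC8D. LRRC8D had 12.1 ± 5.89 FPKM in input and 381 ± 78.1 FPKM in RIP (SD, n = 2; adjusted p = 0.00873). HRH1, the histamine H1 receptor on chromosome 3, rose from 2.32 ± 0.034 to 62.5 ± 17.5 FPKM (SD, n = 2), a log2 fold change of 4.23 (SE 0.48, adjusted p = 0.00873). When the same rule was applied outside chromosomes 1 and 10, a step added after the excess was seen, SRXN1 and HRH1 were followed by PTRH2 (4.03), TRIM13 (3.93), CHST10 (3.57), CCDC71 (3.57), MTSS1L (3.54), ZNF266 (3.51), RAB40C (3.48) and NAIF1 (3.46). This order depends on RIP 2, since without it CHST10 had 4.46, MTSS1L 4.43 and RAB40C 4.40, above PTRH2 and TRIM13 (4.06 each). PTRH2, a mitochondrial peptidyl-tRNA hydrolase, had 8.41 ± 0.98 FPKM in input and 152 ± 4.32 FPKM in RIP (SD, n = 2), and TRIM13, a ubiquitin ligase of the endoplasmic reticulum, had 2.47 ± 0.48 and 51.8 ± 6.69 FPKM.

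None of the 10 largest decreases by the same rule lies on chromosome 1 or 10. SEC61G, a subunit of the protein-conducting channel of the endoplasmic reticulum, had 123 and 118 FPKM in the inputs and was listed at 0 in both RIP libraries. ATP5I, a subunit of ATP synthase, had 91.1 and 74.5 FPKM in the inputs and was also listed at 0 in both. UBL5, SLIRP, PDCD5 and the ribosomal protein gene RPL39 were listed at 0 in RIP 2 only, with 7.64, 5.50, 3.20 and 4.30 FPKM in RIP 1 and between 104 and 427 FPKM in the inputs. RPS29 had 975 and 1109 FPKM in the inputs and 30.6 and 7.61 FPKM in RIP, a log2 fold change of -5.98 (SE 0.71, adjusted p = 0.00873; -5.04 without RIP 2 and -6.92 without RIP 1), and RPL34 had a log2 fold change of -6.22 (SE 1.31, adjusted p = 0.017), or -4.09 without RIP 2 and -8.34 without RIP 1. MT-CYB, the cytochrome b gene of the mitochondrial genome, had 785 and 565 FPKM in the inputs, 88.6 FPKM in RIP 1 and a listed 0 in RIP 2 (adjusted p = 0.0424), and missed the threshold after quantile normalization (adjusted p = 0.0532), with a pseudocount of 0.1 (0.0922) and with no filter (0.108). MTRNR2L8, a nuclear copy of part of the mitochondrial 16S rRNA, had 1024 and 532 FPKM in the inputs and 45.8 and 3.84 FPKM in RIP. Its reads cannot be separated from those of its mitochondrial parent, and ribosomal protein genes likewise share reads with processed pseudogenes.

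Genes of the ZNF family, mostly C2H2 zinc finger transcription factors, were higher in RIP as a list. Of 392 measured, 209 were higher and 3 lower (250 and 4 adjusted over the list alone), and without RIP 1 there were 200 and 7. The median log2 fold change was 1.57 (camera, adjusted p = 1.48e-22, and adjusted p = 0.438 with an estimated correlation). Outside chromosomes 1 and 10, where the test was fitted and adjusted anew on those genes alone, the counts were 210 higher and 4 lower of 363. ZNF496, on chromosome 1, had 9.81 and 7.54 FPKM in the inputs and 139 and 129 FPKM in RIP (log2 fold change 3.81, SE 0.45, adjusted p = 0.00873). ZNF266, on chromosome 19, had a log2 fold change of 3.51 (SE 0.46, adjusted p = 0.00873). ZNF428 went the other way, from 5.06 and 5.86 FPKM in the inputs to 1.15 FPKM in RIP 1 and a listed 0 in RIP 2 (adjusted p = 0.0209), and missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0607) and with no filter (0.0598). Members of this family resemble each other in sequence, so reads may be split between them.

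Chromatin regulators and immediate early genes shared that direction. Among 52 chromatin regulators, 25 were higher and none lower (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.59 (camera, adjusted p = 1.35e-07, and adjusted p = 0.438 with an estimated correlation). In the test redone on genes outside chromosomes 1 and 10, 25 of 49 were higher. ARID1A, the DNA-binding subunit of the BAF remodelling complex, on chromosome 1, had 86.2 and 224 FPKM in RIP against 10.0 and 7.97 FPKM in input (log2 fold change 3.82, adjusted p = 0.00963, and 3.13 without RIP 2). The histone acetyltransferase gene KAT6B, on chromosome 10, had a log2 fold change of 2.65 (SE 0.55, adjusted p = 0.0163), and the histone methyltransferase gene EHMT2 had -1.10 (adjusted p = 0.145). Among 28 immediate early genes, which are transcribed within minutes of a stimulus, 18 were higher and none lower (20 and 0 adjusted over the list alone), with a median of 1.81 (camera, adjusted p = 2.29e-06, and adjusted p = 0.438 with an estimated correlation). DUSP6, a phosphatase of ERK, went from 29.8 and 40.1 FPKM to 418 and 242 FPKM (log2 fold change 3.16, SE 0.53, adjusted p = 0.0111), and the transcription factor gene KLF10 from 9.06 and 12.2 to 72.0 and 59.1 FPKM (2.52, adjusted p = 0.0124). SGK1 had a log2 fold change of -0.97 (adjusted p = 0.14).

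Glycosyltransferase and adhesion genes passed as higher in camera with the preset correlation, and not with an estimated one (adjusted p = 0.722 and 0.438). Of 32 glycosyltransferases, 10 were higher and 1 lower (the same counts adjusted over the list alone). Without RIP 2 these were 21 and 1. The median was 1.24 (camera, adjusted p = 0.000318). The members with the smallest p, B4GALT2 (log2 fold change 3.23, adjusted p = 0.012) and the sialyltransferase gene ST3GAL3 (3.20, adjusted p = 0.0144), both lie on chromosome 1, where RIP 2 was raised, and had 2.69 and 2.5 without RIP 2. Of the list, 9 of the 27 members outside chromosomes 1 and 10 were higher. ST3GAL4, on chromosome 11, was lower (-2.27, adjusted p = 0.0438, and -1.37 without RIP 2), and missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0675) and with no filter (0.0909). Of 31 adhesion and junction genes, 3 were higher and none lower (0 and 0 adjusted over the list alone). These were 10 and 1 without RIP 2, 7 and 2 without RIP 1, and 5 and 0 after quantile normalization. The share of single adhesion genes called higher, 3 of 31, was no larger than that of all genes tested, 1981 of 12848. Adhesion genes had a median of 0.84 (camera, adjusted p = 0.0279, and adjusted p = 0.438 with an estimated correlation). The higher ones included ICAM1, which encodes a ligand of leukocyte integrins, on chromosome 19 (2.10, adjusted p = 0.0382, and 0.0693 without RIP 1, 0.0516 with a pseudocount of 0.1 and 0.0772 with no filter), while the integrin gene ITGAV had -1.29 (adjusted p = 0.111, and 0.0355 without RIP 1). The list missed the threshold without input 2 (adjusted p = 0.0511) and with a filter at 5 FPKM (adjusted p = 0.053).

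The lists of ribosomal protein genes and translation factors were both lower in RIP than in input. Of 77 cytosolic ribosomal protein genes, 71 were lower and none higher (74 and 0 adjusted over the list alone), with a median log2 fold change of -3.99 (camera, adjusted p = 1.11e-20, and adjusted p = 0.438 with an estimated correlation). RPS15A went from 246 ± 1.96 FPKM in input to 6.30 ± 0.21 FPKM in RIP (SD, n = 2; log2 fold change -5.08, SE 0.44, adjusted p = 0.00873), and RPL35A from 866 ± 27.8 to 22.2 ± 4.16 FPKM (-5.24, adjusted p = 0.00873). Of 42 translation factors, 19 were lower and 1 higher, also adjusted over the list alone. These were 21 and 4 without RIP 1, 23 and 2 without RIP 2, and 13 and 2 after quantile normalization. Translation factors had a median of -1.25 (camera, adjusted p = 0.00284, and adjusted p = 0.438 with an estimated correlation). EIF3E, a subunit of the initiation factor eIF3, had -3.89 (adjusted p = 0.00873) and the elongation factor gene EEF1B2 had -3.88 (adjusted p = 0.0091, and -3.26 without RIP 2), while EIF2B1, a subunit of the exchange factor for eIF2, was the member that was higher (1.72, adjusted p = 0.0378).

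Most genes of the respiratory chain, nuclear and mitochondrial, were lower in RIP. Of 62 nuclear-encoded subunits, 53 were lower and none higher (58 and 0 adjusted over the list alone), with a median log2 fold change of -3.39, or -3.34 without the 2 members listed at 0 in both RIP libraries (camera, adjusted p = 1.27e-15, and adjusted p = 0.438 with an estimated correlation). COX6C, a subunit of cytochrome c oxidase, had 155 and 202 FPKM in the inputs and 3.71 and 2.82 FPKM in RIP (-5.39, SE 0.46, adjusted p = 0.00873). Of 13 mRNAs of the mitochondrial genome, 12 were lower (13 adjusted over the list alone), with a median of -3.82 (camera, adjusted p = 3.39e-05, and adjusted p = 0.59 with an estimated correlation). This median was -2.89 after quantile normalization, with 9 lower, -3.04 without RIP 2 and -4.60 without RIP 1. MT-CO3 had 2945 and 3211 FPKM in the inputs and 186 and 77.7 FPKM in RIP (-4.66, adjusted p = 0.00982, and -3.25 after quantile normalization), and MT-ND2 had -3.51 (adjusted p = 0.00991). Of 16 glycolytic genes, 7 were lower and none higher, also adjusted over the list alone. These were 11 and 0 without RIP 2, and 6 and 1 without RIP 1. The median was -1.17, or -1.8 outside chromosomes 1 and 10 and -1.61 without RIP 2 (camera, adjusted p = 0.0295, 0.00154 without RIP 2, and adjusted p = 0.814 with an estimated correlation). GAPDH had 1415 ± 295 FPKM in input and 107 ± 6.46 FPKM in RIP (SD, n = 2; -3.70, adjusted p = 0.0102), LDHB had -2.18 (adjusted p = 0.0238), and HK1, on chromosome 10, had 0.67 (adjusted p = 0.499). HK1 turned with the RIP library left out, with 1.79 without RIP 1 (adjusted p = 0.0141) and -0.45 without RIP 2 (adjusted p = 0.315). This list missed the threshold without RIP 1 (adjusted p = 0.303), without input 2 (0.245) and with a filter at 5 FPKM (0.053).

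Replication-dependent histone genes, whose mRNAs end in a stem-loop rather than a poly(A) tail, were also low in RIP. For them too a difference in poly(A) selection between the groups was not tested. Of 54 measured, 47 were lower and none higher (52 and 0 adjusted over the list alone), with a median log2 fold change of -3.12, or -3.16 without the 2 members listed at 0 in both RIP libraries (camera, adjusted p = 1.25e-14, and adjusted p = 0.438 with an estimated correlation). HIST1H2BB had 375 and 478 FPKM in the inputs and 15.8 and 9.32 FPKM in RIP (-5.01, adjusted p = 0.00873), and HIST1H2AJ had -3.83 (adjusted p = 0.00873). HIST2H4B, on chromosome 1, had 2.18 and 454 FPKM in the inputs, and its level is uncertain because it shares reads with a near-identical copy. Of 31 proteasome subunits, 22 were lower and none higher (23 and 0 adjusted over the list alone), with a median of -1.99 (camera, adjusted p = 1.19e-06, and adjusted p = 0.438 with an estimated correlation). PSMA3 had -4.59 (adjusted p = 0.00873) and PSMB6 had -3.48 (adjusted p = 0.00873), while PSMB5 had 0.17 (adjusted p = 0.783). Of 31 genes of mitosis, 10 were lower and none higher (8 and 0 adjusted over the list alone). These were 19 and 0 without RIP 2, and 9 and 5 without RIP 1. The median was -1.15 (camera, adjusted p = 0.0283, and adjusted p = 0.859 with an estimated correlation). The kinase gene TTK had -3.54 (adjusted p = 0.00907), UBE2C had -2.90 (adjusted p = 0.00943), and MKI67, on chromosome 10 past the part with the excess, had 1.31 (adjusted p = 0.0675, and 0.0184 without RIP 1). This list too missed the threshold without RIP 1 (adjusted p = 0.415), without input 2 (0.245) and with a filter at 5 FPKM (0.0525).

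**Figure D4:**
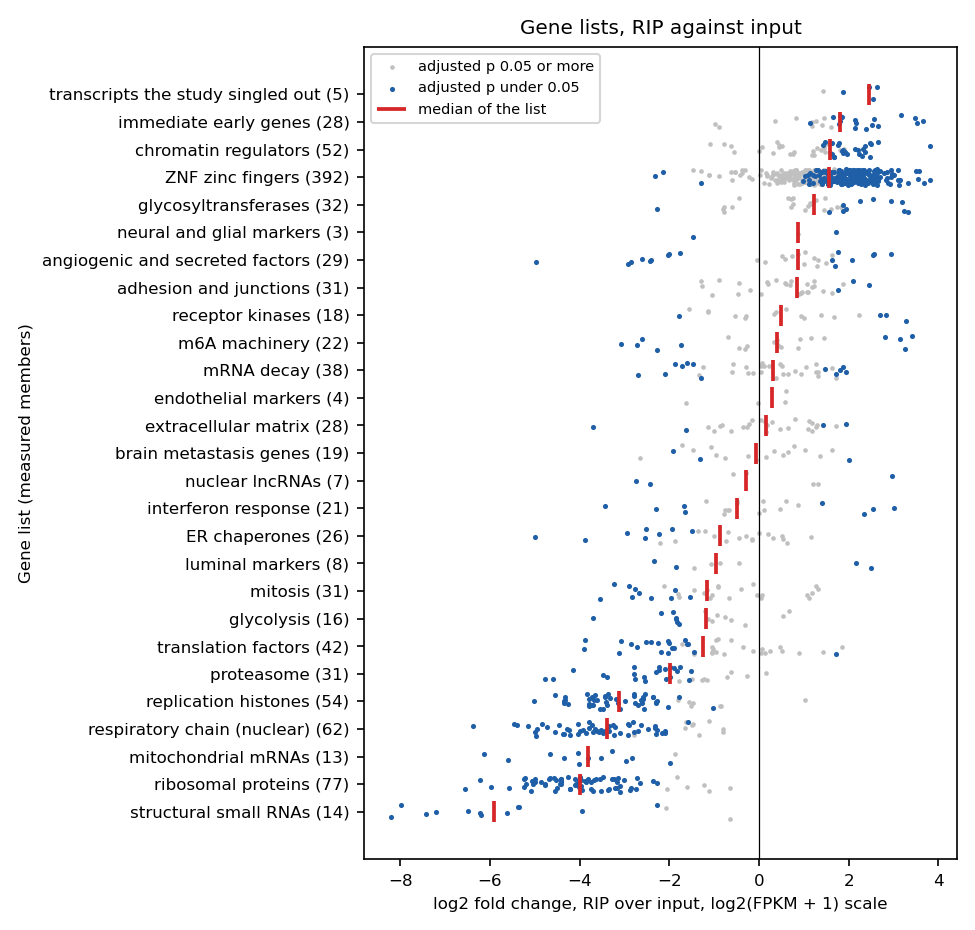
Each point is a gene, placed by its log2 fold change of RIP over input on the log2(FPKM + 1) scale, in blue where adjusted p is under 0.05 and grey otherwise. Red lines mark the medians of the 27 lists, from -5.92 for structural small RNAs to 2.45 for the transcripts the study singled out.

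Genes of the m6A machinery went both ways. Of 22 measured writers, readers and erasers, with YTHDF3 left out, 4 were higher and 5 lower (5 and 5 adjusted over the list alone). Without RIP 2 these were 7 and 5. The list had a median log2 fold change of 0.41 (camera, adjusted p = 0.518). The 4 higher genes were the cytoplasmic readers YTHDF1 and YTHDF2 and the writer subunits RBM15 and RBM15B, all but YTHDF1 named after their values were seen. YTHDF1 had 16.2 and 10.9 FPKM in the inputs and 209 and 76.5 FPKM in RIP (log2 fold change 3.16, SE 0.61, adjusted p = 0.0143, and 2.44 without RIP 1). YTHDF2, with 79.7 and 695 FPKM in RIP 1 and RIP 2, had 3.26 (adjusted p = 0.0411, and 1.70 without RIP 2), and RBM15, with 68.5 and 309 FPKM, had 3.42 (adjusted p = 0.0187, and 2.34 without RIP 2), both on chromosome 1, and RBM15B had 2.82 (adjusted p = 0.0201, and 3.63 without RIP 2). The rRNA methyltransferase genes METTL5, with 47.5 and 47.1 FPKM in the inputs and 4.57 and 4.93 FPKM in RIP (-3.07, SE 0.45, adjusted p = 0.0091), and ZCCHC4 (-2.28, adjusted p = 0.0122) were lower. So were the genes of the readers IGF2BP3 (-1.75, adjusted p = 0.037), HNRNPA2B1 (-2.71, adjusted p = 0.0338) and HNRNPC (-2.62, adjusted p = 0.0258), also named after their values were seen.

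Secreted factors and interferon-response genes also went both ways, with a balance that depended on RIP 2. Of 29 angiogenic and secreted factors, 7 were higher and 9 lower (8 and 9 adjusted over the list alone). Without RIP 2 these were 14 and 9. Their median was 0.87, with a mean of 0.11 and a camera adjusted p of 0.351. CXCL8, which encodes interleukin-8, had 702 and 515 FPKM in the inputs and 23.5 and 14.1 FPKM in RIP (log2 fold change -4.97, SE 0.52, adjusted p = 0.00873), EREG had -2.61 (adjusted p = 0.0124), and BMP4, a bone morphogenetic protein gene, had 11.3 and 8.84 FPKM in input and 154 and 45.6 FPKM in RIP (2.95, adjusted p = 0.0193, and 2.08 without RIP 1). Of 21 interferon-response genes, 4 were higher and 4 lower, also adjusted over the list alone (3 and 8 without RIP 2). The median was -0.48 (camera, adjusted p = 0.949). Outside chromosomes 1 and 10, 1 of 15 was higher and 4 were lower, with a median of -0.66. IFIT1, on chromosome 10, had 3.02 (adjusted p = 0.0135), with 335 FPKM in RIP 1 and 595 FPKM in RIP 2. BST2, which encodes tetherin, had 26.4 and 16.3 FPKM in the inputs, 3.10 FPKM in RIP 1 and a listed 0 in RIP 2 (adjusted p = 0.019), and missed the threshold with a pseudocount of 0.1 (adjusted p = 0.059) and with no filter (0.0535).

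Genes linked to brain metastasis of breast cancer in earlier work, apart from the 5 above, did not stand apart as a list. Of 19 measured, 1 was higher and 2 lower (0 and 2 adjusted over the list alone). These were 3 and 4 without RIP 2, 2 and 5 without RIP 1, and 2 and 1 after quantile normalization. Their median of -0.06 became 0.43 after quantile normalization (camera, adjusted p = 0.949). CXCR4, a chemokine receptor gene, had 3.0 and 2.45 FPKM in the inputs and 22.4 and 8.47 FPKM in RIP (2.0, adjusted p = 0.0405, and 1.35 without RIP 1), and missed the threshold with a pseudocount of 0.1 (adjusted p = 0.0508) and with no filter (0.0808). CSF3 was lower (-1.93, adjusted p = 0.0225), and SERPINI1, which encodes neuroserpin, was listed at 0 in both RIP libraries and at 1.64 and 1.36 FPKM in input (adjusted p = 0.0159, 0.0542 after quantile normalization and 0.051 in limma without trend). Of 18 receptor kinases, 3 were higher and 1 lower (3 and 0 adjusted over the list alone). These were 10 and 0 without RIP 2, and 3 and 5 without RIP 1. Receptor kinases had a median of 0.49 (camera, adjusted p = 0.226). All 3 of the higher ones, ROR1 (2.69, adjusted p = 0.0147), EPHB2 (2.84, adjusted p = 0.0153) and EPHA2 (3.27, adjusted p = 0.0206), the last named after its values were seen, lie on chromosome 1, and had 2.12, 2.26 and 2.48 without RIP 2. RYK was lower (-1.78, adjusted p = 0.0477, and 0.0697 without RIP 2, 0.0594 with a pseudocount of 0.1 and 0.0848 with no filter). The list passed in camera without RIP 2 (median 1.67, adjusted p = 0.0305) and without input 1 (median 1.07, adjusted p = 0.0284), and its median was -0.26 without RIP 1.

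The remaining lists did not pass in camera. Of 28 extracellular matrix genes, 2 were higher and 2 lower (0 and 0 adjusted over the list alone, 4 and 3 without RIP 1; median 0.17, adjusted p = 0.351), with ADAMTS1 at 1.95 (adjusted p = 0.0258) and the matrix metalloproteinase gene MMP3 at -1.62 (adjusted p = 0.0203). The median of this list was -0.05 outside chromosomes 1 and 10, and the list passed without input 1 (median 0.53, adjusted p = 0.0376). Of 38 mRNA decay factors, 5 were higher and 7 lower (0 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.351). These were 9 and 7 with RIP 1 or RIP 2 left out, and 8 and 5 after quantile normalization. PAN2 was at 1.73 (adjusted p = 0.0179) and CNOT7, a deadenylase of the CCR4-NOT complex, at -2.69 (adjusted p = 0.0246, and -1.87 without RIP 2). Of 26 chaperones and translocation factors of the endoplasmic reticulum, 8 were lower and none higher (7 and 0 adjusted over the list alone, 10 and 2 without RIP 2; median -0.87, adjusted p = 0.0628, and 0.0238 without RIP 1). Among them SSR3 had -2.95 (adjusted p = 0.0106) and SSR1 had -2.54 (adjusted p = 0.0146), while SEC61A1 had 1.17 (adjusted p = 0.119, and 0.0239 without RIP 2). Of 7 long non-coding RNAs from a list drawn up as nuclear, 1 was higher and 2 were lower, also adjusted over the list alone. Where in the cell each of them lies was not checked. Their median was -0.29 (0.46 outside chromosomes 1 and 10 and 0.10 without RIP 2), with a mean of -0.08 and a camera direction that was up (adjusted p = 0.949). TUG1 had 29 and 15.6 FPKM in the inputs and 233 and 131 FPKM in RIP (2.98, adjusted p = 0.0133), GAS5, on chromosome 1, had -2.75 (adjusted p = 0.0161), and the other lower gene, MALAT1, named after its values were seen, had -2.43 (adjusted p = 0.0192).

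Markers of other cell types showed no common direction. Of 8 luminal epithelial markers measured, 2 were higher and 2 lower (2 and 3 adjusted over the list alone; median -0.97, camera adjusted p = 0.631). These were FOXA1 (2.49, adjusted p = 0.0226, and 1.8 without RIP 1), CLDN4 (2.16, adjusted p = 0.0208), KRT18 (-1.85, adjusted p = 0.0264) and EPCAM (-2.33, adjusted p = 0.0287, and 0.0593 without RIP 2), the last named after its values were seen. Of 3 neural and glial markers, MBP had 1.72 (adjusted p = 0.037) and SYT1 had -1.47 (adjusted p = 0.0252), the same calls as adjusted over the list alone, with a median of 0.87 (camera, adjusted p = 0.723). Of 4 endothelial markers none passed, also adjusted over the list alone, with a median of 0.28 (-0.39 without RIP 1 and -0.10 without RIP 2), a mean of -0.12 and a camera adjusted p of 0.949. ESAM had -1.62 (adjusted p = 0.0913) and passed without RIP 1 (adjusted p = 0.0166), and KDR had 0.60 (adjusted p = 0.532), with 1.74 without RIP 2 (adjusted p = 0.0191) and -0.54 without RIP 1. Of the 12 immune and blood markers 1 was measured, and that list was not tested.

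The ratios of RIP to input taken within each title suffix correlated across genes and differed on chromosomes 1 and 10. One input and one RIP library share each of the suffixes in the titles, and the log2 ratios within the suffixes correlated with Pearson's r = 0.816 and Spearman's rho = 0.824 across the 12848 genes, which are not independent replicates. At least 2-fold higher with both suffixes were 2555 genes, where 1064 would be if the ratios were independent, and at least 2-fold lower with both were 3568, where 1559 would be. Opposite 2-fold differences were found for 156 genes. The median log2 ratio of protein-coding genes was 0.10 with the first suffix and 1.94 with the second on chromosome 1, and 0.19 and 1.06 on chromosome 10. Chromosome 1 held 393 of the genes higher with both suffixes (15.4%), against 10.6% of the genes tested, and outside chromosomes 1 and 10 the counts were 2011 higher and 3288 lower.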

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

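The tests outside chromosomes 1 and 10 and with RIP 2 adjusted by position were chosen after the data were seen. The count of genes higher in RIP, 1981, became 3085 after quantile normalization, 3575 with RIP 2 adjusted by position and 718 with no filter on low values, where 18496 genes were tested. With each library left out in turn it ranged from 0 to 3515, and the count of lower genes, 3126, ranged from 0 to 3933. The count was 0 in both directions without input 1 and without input 2, where limma takes the spread from the RIP libraries alone and the lone input is assumed to vary like them, and 737 and 608 genes were higher and 2299 and 2257 lower at an unadjusted p under 0.05. Without RIP 1, the counts were 2471 higher and 3933 lower, and without RIP 2 they were 3515 and 3742, with the lone RIP library assumed to vary like the inputs. All other settings gave counts within 1.5 times of the main ones: median centring 2899 and 2943, a filter at 5 FPKM 1844 and 2684, a pseudocount of 0.1 1491 and 2623, limma without trend 1876 and 2989, and genes outside chromosomes 1 and 10 1814 and 3119. Of the 5107 calls, 4757 were shared with the same sign after quantile normalization and 4906 with RIP 2 adjusted by position. Apart from the number of genes tested and the source of the spread, the cause of these shifts was not tested.

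With the title suffix as a replicate block, 2477 genes were higher and 3466 lower. Deviations of libraries with the same suffix from their group means correlated across genes with r = 0.214 (0.257 outside chromosomes 1 and 10), and since there are only 2 suffixes whose meaning is not stated, the libraries were not treated as paired.

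With an estimated inter-gene correlation the number of lists higher in camera went from 6 to 0 and the number lower from 9 to 0, with adjusted p of 0.438 or more for each of these 15 lists. The correlation was estimated from 4 libraries, and this form of the test has only their few residual degrees of freedom. The lost calls therefore do not by themselves show that the genes of a list move together. How much each part contributes was not tested. The lists were not run with median centring, with no filter on low values or in limma without trend. Over the other settings the lists gave 257 values on the same side of the threshold, 8 that lost a call and 4 that gained one, all in the same direction, and those 12 are given with their lists in the results above. The 99 named genes gave 1038 values on the same side, 209 that lost a call and 11 that gained one, and none of the called genes changed direction. Of the lost calls, 88 came from leaving out input 1, 88 from leaving out input 2 and 20 from testing without a filter, 10 of them RPL34 (adjusted p = 0.0533), RAB40C (0.0611), LDHB (0.0506), MMP3 (0.0528), EIF2B1 (0.064), PAN2 (0.0502), CNOT7 (0.058), FOXA1 (0.0515), SYT1 (0.062) and MBP (0.0623), and the others are given in the results above except where not reported. With RIP 2 adjusted by position, EGFR (adjusted p = 0.0177), SEC61A1 (0.0177) and MKI67 (0.0258) gained a call, and with the replicate block ESAM did (0.029). Spearman's rho between the RIP to input ratios of the suffixes, 0.824, was 0.851 with a filter at 5 FPKM, 0.81 with a pseudocount of 0.1, 0.881 outside chromosomes 1 and 10 and 0.884 with RIP 2 adjusted by position. The depth of RIP 2, about 3110000 reads against 6140000 to 10400000 in the others, limits it most for transcripts of low level, and a gene listed at 0 there is not shown to be absent.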

Other observations

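The comparisons of RNA classes, gene families, exon numbers and transcript lengths, and the tests of position along chromosomes 1 and 10, of the inputs on chromosome 1, of the level of olfactory receptor genes and of exon number as a cause, and the repeat of the position test with GC content and length removed, were chosen after the data were seen. Some classes of RNA other than mRNA differed between RIP and input in their medians, although no class was tested as a whole. Processed pseudogenes, most of which are copies of abundant short mRNAs with which they share reads, had a median log2 fold change of -1.53, with 620 lower and 38 higher of 1109. Small nucleolar RNAs had a median of -2.92, with 125 lower and 1 higher of 160. Long intergenic non-coding RNAs had a median of 0.70, with 34 higher and 17 lower of 132, and antisense genes 0.94, with 39 higher and 11 lower of 116, while the use of strand in counting is not stated, so reads of an antisense gene and its partner may not be separable. Small nuclear RNAs (2 higher and 52 lower of 60, median -3.61) and the class misc_RNA (0 and 71 of 74, -3.48) leaned strongly down, and transcribed unprocessed pseudogenes leaned up (17 and 5 of 93, 0.61). Less one-sided classes were also present: processed transcripts had 7 higher and 9 lower of 54 (median -0.26, and 0.11 after quantile normalization), transcribed processed pseudogenes 14 and 20 of 79 (-0.40) and unprocessed pseudogenes 5 and 10 of 43 (-0.55). The protein-coding genes had a median of 0.12, or -0.03 outside chromosomes 1 and 10. After quantile normalization the medians were -1.19 for processed pseudogenes, -2.66 for small nucleolar RNAs, 1.06 for long intergenic RNAs and 1.23 for antisense genes, all of the same sign as before, and 0.34 for protein-coding genes.

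Some families of genes that share the start of their symbol passed apart from the lists. Among 53 families with at least 20 measured protein-coding members, tested with Fisher's exact test, one-sided, in each direction (106 tests) against all 10852 protein-coding genes, ZBTB genes, transcription factors with a BTB domain, were higher more often than the rest (15 of 37, adjusted p = 0.00672, and 12 of 28 outside chromosomes 1 and 10). MRPL genes of the mitochondrial ribosome were lower more often (21 of 49, adjusted p = 0.00297), as were UBE genes, mostly ubiquitin-conjugating enzymes (16 of 39, adjusted p = 0.0206). These families were not matched on transcript length, which went with recovery outside chromosomes 1 and 10. There, 48.2% of 1854 protein-coding genes of 177 to 2024 nt were lower, with a median log2 fold change of -1.6. Of 1854 genes of 5859 to 34526 nt, 8.6% were lower (median 0.68). The shares called higher were 6.3% and 18.9%. Whether length or input level accounts for these families, or for lists other than ribosomal protein and respiratory chain genes, was not tested.

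The excess of chromosomes 1 and 10 in RIP 2 varied with position: median log2 differences from RIP 1 in 37 bins of 10 Mb, which went from 1.79 in the first 3 bins of chromosome 1 up to 2.64 between 60 and 90 Mb and down to 1.04 in its last 3, had Spearman's rho = -0.87 with their place along chromosome 1 and then chromosome 10, the next chromosome when names are sorted as text, and chromosome 2 was raised by only 0.11 over the others. With the trend in GC content and transcript length removed, the median was 2.68 in the first 3 bins of chromosome 1, at most 2.87 in a later bin and 1.44 in its last 3, began at 1.61 on chromosome 10 and ended there at -0.12 (rho = -0.95). The inputs differed on chromosome 1 by 0.028 more than elsewhere (95% bootstrap interval over genes -0.028 to 0.058). This argues against a copy number or expression difference between cultures only if input 2 and RIP 2 share a culture, which the labels do not say. GC content or length is argued against by the excess of 2.29 (2.22 to 2.35, again over genes) that was left after regression on them. A candidate explanation is that reads of RIP 2 were added, or lost elsewhere, while they were in an order sorted by chromosome name, a hypothesis found and tested on the same values. No biological explanation was tested beyond the difference between cultures.

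The low recovery of ribosomal protein and respiratory chain mRNAs went beyond that of genes matched on annotated length and input level. The 126 such genes outside chromosomes 1 and 10 had a median log2 fold change of -3.85, against 0.01 for the 9142 other protein-coding genes. Compared with the 20 other genes nearest in transcript length they were lower by a median of -2.08 (95% bootstrap interval -2.32 to -1.93), with the 20 nearest in input level by -1.79 (-1.98 to -1.52), and with the 20 nearest in both by -1.25 (-1.48 to -1.04), where the matched genes had a median of -2.78. Annotated length and level thus go with a large part of the difference and leave a remainder. It was -1.43 (-1.75 to -0.90) for the 45 genes with matches within 0.2 SD, a check added later because close matches were few. These intervals come from resampling genes and leave out the variation between libraries. Length here is that of the longest annotated transcript, 7062 nt for RPS29 and 2203 nt for RPS15A. Where a shorter form is expressed, the matched genes are too long, so the remainder may still hold an effect of length. A lower binding of these mRNAs by YTHDF3 stays open. So does a loss through the length of the forms expressed or through other properties of these mRNAs, which was not tested.

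Among protein-coding genes outside chromosomes 1 and 10 and the mitochondrial genome, transcripts with few exons were recovered more than those with many. The median log2 fold change was 1.45 for 232 single-exon genes and 1.04 for 1047 genes with 2 or 3 exons. It was -0.35 for 4162 genes with 4 to 10 exons and -0.10 for 3827 with more. The last lies closer to 0 than the 0.23 by which quantile normalization moved the median of all genes. The order of the first 3 classes was the same in both suffixes. Genomic DNA in the RIP libraries would add reads to silent single-exon genes too, and the share of 375 olfactory receptor genes above 0 was 5.6% in RIP 1 and 1.33% in RIP 2 against 2.67% and 2.13% in the inputs, at most 3.47 percentage points higher, which lies between the limits set beforehand and does not decide. A test added after these shares were seen argues against genomic DNA as the source of the shift: with the mean FPKM of olfactory receptor genes in each library subtracted from its values, the median of all 232 single-exon genes, called or not, went from 1.447 to 1.448 (a fall of -0.06%, which is no fall), while the mean level as a share of the median rise in the 105 single-exon genes called higher (at most 0.046%) adds little, since a rise was fixed by that selection. The longest exon had a partial rho of -0.094 (-0.113 to -0.074), given exon number, transcript length and input level, against the positive value that long exons as the cause would give, but rho was 0.361 without these terms, so long exons are argued against only as far as these terms can be separated from them. With exon number, given length and input level, the partial rho was -0.244 (-0.262 to -0.226), consistent with the hypothesis that splice junctions, near which m6A is sparse, lower recovery, although rho was only -0.086 without these terms, that test was chosen after the pattern was seen and m6A itself was not measured.

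A further hypothesis was that transcripts with more matches to the m6A consensus motif DRACH are recovered more. Across 9268 protein-coding genes outside chromosomes 1 and 10, motifs per kilobase had a partial Spearman's rho of 0.145 (95% bootstrap interval 0.128 to 0.164) with the log2 fold change, given transcript length, GC content and input level, and 0.132 and 0.15 for the ratios of the separate suffixes. Without these terms rho was 0.036, so the relation may rest on how they are modelled. Transcript length had a larger partial rho, 0.359, given input level and GC content, and GC content had 0.278, given length and input level. The largest in size was that of input level, -0.399 given length and GC content (rho -0.473 without these terms). Input level is also the subtracted term of the fold change, so they are not independent. Genes are not independent replicates, and these intervals cover only the sampling of genes.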
